A study of Caenorhabditis elegans with 15 samples.

How the data were processed

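Poly(A) RNA from whole Caenorhabditis elegans was sequenced in 15 libraries, 3 from each of 5 strains. The strains were the parent strain, in which smn-1 lies between FRT sites, and 4 lines that also express the FLP recombinase. FLP serves to remove smn-1 in the intestine, in muscle, in all neurons or globally. Groups and replicate numbers were taken from the sample labels. The labels name a library kit that does not mark the strand, and they do not say whether reads were counted by strand.

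The deposited values are counts of reads per gene, made by the authors with STAR and HTSeq on genome build WBcel235, as the submitters' processing notes name them, with no versions given. All 15 columns of counts were used. HTSeq's summary lines gave 0.251 to 0.903% of reads in no gene, 1.48 to 2.29% in more than 1 gene and 2.26 to 12.2% aligned to several places.

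The deposited table holds a pair of blocks side by side. The 9 control, muscle and global columns have 46726 gene rows and the gene identifiers. The 6 intestinal and neuronal columns have 46926 gene rows, 200 more, so that from row 752 on most identifiers printed beside them belong to other genes. Of all rows matched as described below, 836 kept the printed identifier. Levels are counts scaled to a library total of 1000000 (CPM). Read as printed, the mean log2 levels of the blocks correlated at 0.221 across genes with at least 1 CPM. Rows of the longer block were therefore matched to identifiers from the counts alone, by an alignment of the 2 blocks' ordered levels with a pair hidden Markov model, keeping matches with a posterior of at least 0.99. Of 14220 genes with at least 1 CPM, 13581 (95.5%) were matched and 639 were not, and were not analysed here. The match was then checked against the sorted gene list of a WBcel235 annotation that also holds 46926 genes: the order of that list gave the same identifier for 13574 of the 13581 genes (99.9%), and the other 7 were left out. Over the 13581 matched genes with at least 1 CPM the correlation was 0.963, and 22363 genes were matched in all. In a test, rows were removed from and added to the muscle columns at random, and these were aligned with the control columns. Of the 16524 rows with at least 30 control counts 95.3% were matched, and 99.97% of these to the right gene. Both sets of columns share their gene models, so this does not measure errors across the blocks. The joined genes hold 97.1 to 98.8% of each library's gene counts. This matching was chosen after the data were seen. The longer block was counted on another set of gene models, so that the gene set and the intestinal and neuronal groups are confounded in every comparison across the blocks. Any other difference in processing between the blocks would be confounded with these groups too. Coordinates and symbols are from the WBcel235 annotation, and genes whose exons overlap those of another gene on either strand are named as such.

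Libraries held 20776240 to 171926809 gene counts. A level of 0 is given against a floor of 3 counts per library, and folds against a group at 0 are lower bounds from that floor. Floors cover counting error only.

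The tests, gene lists, naming rule and alternatives were fixed before the data were examined, except those said to be chosen later. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 16786 genes, and libraries were scaled by TMM. All 15 libraries were fitted with 1 coefficient per group, which left 10 residual degrees of freedom, and 10 comparisons were tested with edgeR's robust quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes with an adjusted p under 0.05 were called. Levels are TMM-scaled CPM, given as mean ± SD, n = 3 libraries in every group. Fold changes are log2 values with standard errors from the same fit. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between libraries. The common biological coefficient of variation was 48.9%. Simulated counts were drawn for each gene separately, from the control's mean level and the spread fitted to these libraries. Known changes were put into a small set of genes that were not low in the control. There 2-fold changes were called in 3 to 11.9% of the genes that held one, 4-fold changes in 59.7 to 64.2% and 8-fold changes in 78.8 to 81.8%, with 1 to 6 false calls among 100 to 107 calls per comparison with the control. These draws hold no stage or replicate structure shared by genes and few changed genes. They therefore do not measure false calls in the real libraries or power for genes at low levels. Matching used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.

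Gene lists written in advance were tested with camera (limma 3.58.1), at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists that had at least 3 tested members. The lists hold SMN, Sm and Lsm proteins, splicing factors, body wall muscle, pharynx, intestine and vitellogenins, and pan-neuronal genes, neuropeptides, neuromuscular junction receptors and insulin-like peptides. Others hold germline and oogenesis, spermatogenesis, early embryo, cuticle collagens, molting, epidermal antimicrobial peptides, glia, coelomocytes and excretory cell, histones and ribosomal proteins. The rest hold oxidative phosphorylation, innate immunity, the intracellular pathogen response, the heat shock response, unfolded protein responses of the endoplasmic reticulum and of mitochondria, detoxification, DAF-16 targets, cell death and DNA damage, fasting and fatty acid oxidation, fatty acid synthesis and storage, and nonsense-mediated decay. A further 3 lists, of major sperm proteins, mitochondrially encoded genes and smn-1 neighbours, had too few tested members to be tested as lists.

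Named genes were those of a rule set in advance. They are smn-1, its listed neighbours and the 4 promoter genes. Further genes were named per comparison with the control, among called genes whose 3 knockout levels all lie outside the 3 control levels and whose mean is at least 5 CPM, namely the 8 largest rises and 8 largest falls with a gene-class name and the 2 largest of each without one. Up to 4 members of each list described and 6 genes per direct contrast of knockouts were added. Genes named outside the rule are said to be chosen after their values were seen.

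Overlaps between a tissue knockout and the global knockout share the 3 control libraries, which are too few to split. They are given beside the number that independent lists would share and the number in 20 simulations of unchanged groups that share the controls, which hold no effects. Replicate numbers were checked for pairing by correlating residuals of libraries with the same number. A comparison was taken as paired only if the lowest of its 3 correlations passed a low bound. By this rule they paired in muscle against control (r 0.66, 0.20 and 0.83), intestinal against neuronal (0.17, 0.56 and 0.18) and muscle against neuronal (0.48, 0.86 and 0.76). The other 7 comparisons, neuronal against control (0.02, 0.37 and 0.76) among them, did not pass it. Yet for 12 of the 15 libraries the best match in another group had the same replicate number. Replicate number thus carries structure beyond the paired comparisons. The fit with the replicate number as a block is an alternative.

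The alternatives set in advance were RLE and upper-quartile scaling, scaling without germline, yolk, embryo, collagen and molting genes, a filter of 1 CPM in 3 libraries and no filter. Others were a fit without robust dispersion, only the groups compared, the replicate block, an adjusted p under 0.01, a minimum fold of 1.5, DESeq2 1.42.0, an estimated inter-gene correlation and leaving out each of the 15 libraries. Added after the data were seen were rows paired by annotation order, identifiers as printed, genes without overlap, the 9 or the 6 libraries of a block alone, 3 libraries with high yolk and oogenesis levels left out (the third of control, muscle and neuronal), and covariates for the summed vitellogenin, oogenesis and spermatogenesis levels (stage covariates). Figures were drawn with matplotlib 3.10.9.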

Results

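RNA levels were measured in whole worms of 5 strains, with 3 libraries each. In every strain the smn-1 gene lies between FRT sites, the targets of the FLP recombinase. smn-1 encodes the worm survival motor neuron protein, which helps to assemble the small nuclear ribonucleoproteins of the spliceosome. The control is the parent strain without FLP. The 4 knockouts make FLP from a promoter chosen to remove smn-1 in intestine (elt-2 promoter), muscle (myo-3), neurons (rgef-1) or globally (mex-5). Gene counts per library were 92264635, 59349181 and 20853440 in the control. They were 59054835, 50900672 and 171926809 in the intestinal and 79304667, 51338050 and 90823392 in the muscle knockout. The neuronal libraries held 96810098, 117318537 and 73835032, and the global libraries 23244815, 36453161 and 20776240. The first principal component held 51% of the variance and placed the 3 global libraries between 121.2 and 177.4. The second libraries of the muscle, neuronal and intestinal knockouts followed at 61.2, 35.5 and 39.5, and the 9 others lay below 0. Yolk protein transcripts (vitellogenins, made by the intestine of adult hermaphrodites) differed widely within strains, from 282.9 to 38930 CPM in summed level, both in neuronal libraries.

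smn-1 transcripts (WBGene00004887, chromosome I, 9511174 to 9512236 on WBcel235) were low in the global knockout and near the control level in the other knockouts. The control libraries held 28, 25.1 and 35 CPM (mean 29.4 ± 5.11), and the global libraries 3.24, 0.723 and 0.251 (1.4 ± 1.61). The level fell by 4.38 on the log2 scale (SE 0.67, adjusted p = 0.00144). Levels were 24.1 ± 3.61 CPM in the intestinal knockout (log2 fold change -0.28), 30.2 ± 6.04 in the muscle knockout (0.04) and 33 ± 10.3 in the neuronal knockout (0.17), each with an adjusted p of 1, so that whole-worm levels do not show the deletion in these 3. In direct contrasts smn-1 was higher than in the global knockout by 4.10 in the intestinal (adjusted p = 0.00255), 4.42 in the muscle (0.00168) and 4.55 in the neuronal knockout (0.000907). Without control replicate 2 or muscle replicate 3 the muscle value was -0.06 or -0.10, and without neuronal replicate 3 the neuronal value was -0.06. The exons of smn-1 overlap another gene on the opposite strand, and rgef-1 is an overlapping gene too. Neither its neighbours klp-16 and set-32 nor the promoter genes elt-2, myo-3, rgef-1 and mex-5 were called in any comparison with the control. In the global knockout their values were -1.65 (adjusted p = 0.0782), -0.09 (0.829), 0.31 (0.274), 0.34 (0.539), 0.63 (0.2) and -1.66 (0.25).

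**Figure D1:**
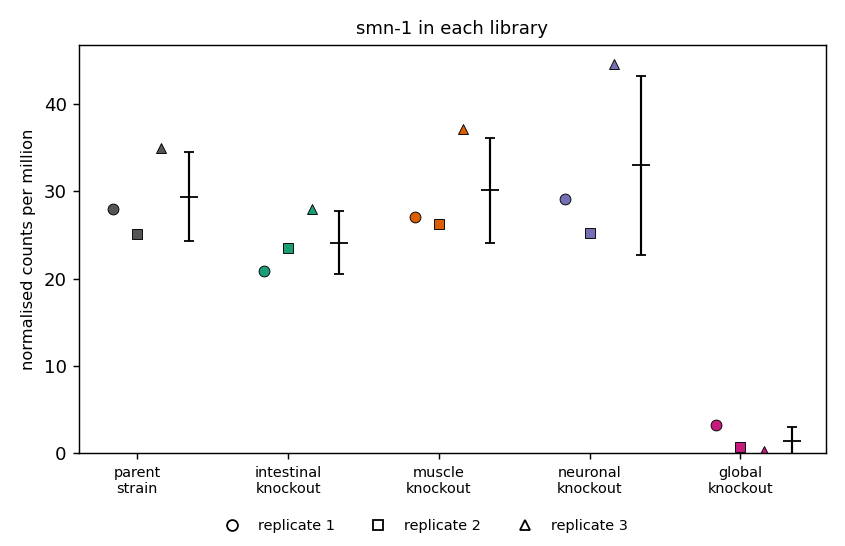
smn-1 level in each of the 15 libraries (points, CPM on a linear axis) by strain, with the mean and SD of 3 libraries beside them. The 3 global libraries lie between 0.251 and 3.24, below the 3 control libraries, which lie between 25.1 and 35.

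The comparison of the global knockout with its parent asks what loss of smn-1 throughout the worm does to the transcriptome. Each knockout is a single strain that makes FLP, and the control makes none. In every comparison with the control, FLP itself and strain background therefore coincide with loss of smn-1. Genes of the intracellular pathogen response, which worms switch on against microsporidia and viruses, had the highest median change of the 32 lists, and sperm genes the lowest. Of 40 tested response genes 29 rose and 0 fell, and of 44 spermatogenesis genes 40 fell and 1 rose. Across all 16786 genes tested, 2370 were higher and 2364 lower by edgeR's quasi-likelihood test, and 1815 and 1894 of these by at least 2-fold. This balance turns with the setting: 1993 and 2661 with RLE scaling, 1688 and 2711 with no filter, and 2611 and 3325 by DESeq2. Among genes with a mean of at least 5 CPM whose 3 global levels all lie outside the control levels, the largest rises were in the F-box genes fbxa-163 (WBGene00015598, chromosome II, 1609252 to 1610730) and fbxa-158 (WBGene00015602). fbxa-163 was at 107 ± 27.2 against 0.103 ± 0.0778 CPM (log2 fold change 9.78, SE 0.98, adjusted p = 0.000129). fbxa-158 rose by 9.11 (SE 0.81, adjusted p = 8e-05). They were followed by clc-32 (8.41), the saposin-like gene spp-20 (8.38), pals-33 (8.09) and pals-14 (7.66). A copy of numr-1, a gene of the response to metals (7.47), and fipr-24 (7.36) came next. Among genes without a class name, F48C1.9 (7.97) and Y68A4A.13 (7.87) rose most. numr-1 is carried by a pair of near-identical genes, and the other copy rose by 3.97 (adjusted p = 0.0012), so that reads cannot be assigned to one copy with certainty. The largest falls within the same limits were those of F17E9.4 (-7.22), of ule-5 (-6.66), ule-3 (-6.39) and ule-4 (-5.95), which encode uterine lumen proteins, and of F54F7.3 (-6.20) and the eggshell gene perm-2 (-6.0). Next came the adult cuticle collagen col-19 (11.2 ± 6.85 against 713 ± 780 CPM; -6.0, SE 1.94, adjusted p = 0.0358) and col-124 (-5.91). The nematode-specific peptide genes nspd-3 (-5.99) and nspd-2 (-5.90) fell as far. perm-2, ule-4 and col-124 overlap other genes. The call of col-19 was lost without control replicate 2 or 3 or global replicate 1, 2 or 3 (adjusted p = 0.0535, 0.0951, 0.0812, 0.107 and 0.0992), and ule-5, ule-3, perm-2, col-124, F17E9.4, nspd-2 and nspd-3 also lost theirs without at least 2 single libraries. The count of called genes was 3102 without control replicate 2 (1154 higher and 1948 lower), 2862 without global replicate 3 (1302 and 1560) and 1806 with stage covariates (1038 and 768). With the covariates 58 named genes stayed called, 61 did not, and grl-27, cut-4 and snf-3 changed sign (0.29, 0.14 and -0.46, with adjusted p = 0.882, 0.897 and 0.446).

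Lists of the intracellular pathogen response, DAF-16 targets, innate immunity, antimicrobial peptides and detoxification rose in the global knockout. In the intracellular pathogen response list, 29 members rose and 0 fell (35 and 1 adjusted over the list alone; median log2 fold change 3.16, adjusted p = 4.69e-24, and adjusted p = 0.053 with an estimated correlation). fbxa-182 went from 1.55 ± 0.59 to 54.9 ± 5.63 CPM (5.13, SE 0.39, adjusted p = 3.72e-05), F26F2.1 rose by 6.30 and pals-26 by 5.15. The summed level of the list was 783.9, 519.3 and 805.5 CPM in the global libraries and 141.6 to 258.2 in the 12 others. Of 27 genes known to be raised by DAF-16, the FOXO factor of insulin signalling, 16 rose and 0 fell (19 and 0 adjusted over the list alone; median 1.86, adjusted p = 1.27e-10, and adjusted p = 0.053 with an estimated correlation). Among them were the desiccation gene lea-1 (1.72), the catalases ctl-1 (2.70) and ctl-2 (2.35) and the gluconeogenic enzyme pck-1 (1.64). Innate immunity genes rose in 21 of 62 cases and fell in 3 (25 and 5 adjusted over the list alone; median 0.70, adjusted p = 0.000224, and adjusted p = 0.518 with an estimated correlation). Called members included the lectin clec-52 (142 ± 24.3 against 15.4 ± 1.84 CPM, 3.20), irg-3 (1.79), the lysozyme lys-3 (4.60) and hlh-30 (1.66), a regulator of autophagy. Epidermal antimicrobial peptides rose in 8 of 18 cases and fell in 0 (10 and 0 adjusted over the list alone; median 1.91, adjusted p = 0.000139, and adjusted p = 0.518 with an estimated correlation). Called members included cnc-7 (8.10), nlp-29 (3.29), nlp-31 (2.66) and cnc-2 (4.2). Among 200 detoxification genes 56 rose and 8 fell (63 and 8 adjusted over the list alone; median 0.66, adjusted p = 0.000139, and adjusted p = 0.518 with an estimated correlation). These included the glutathione transferases gst-15 (4.01) and gst-7 (1.85). pals-26, lea-1 and ctl-2 overlap other genes. With stage covariates the innate immunity and detoxification lists were not called (adjusted p = 0.538 and 0.636).

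**Figure D2:**
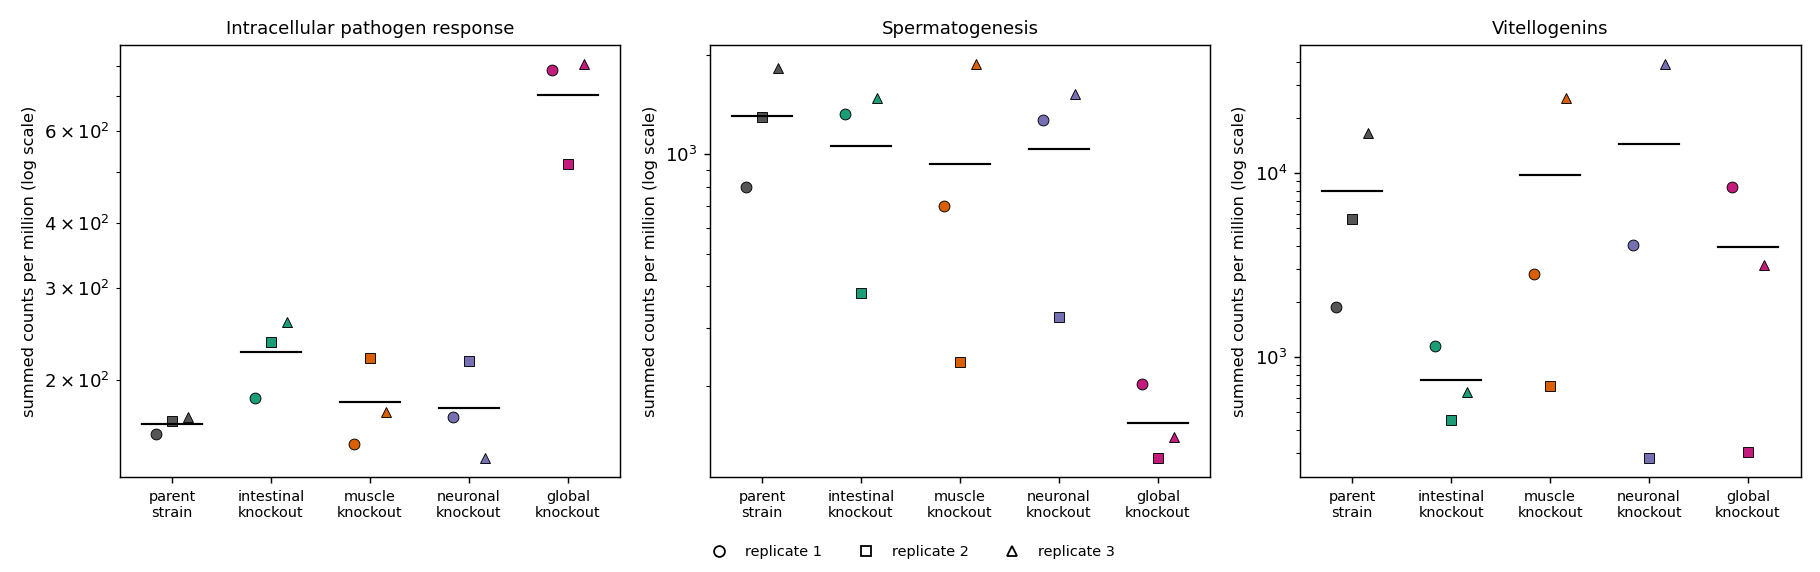
Summed CPM (log axis) of the intracellular pathogen response, spermatogenesis and vitellogenin lists in each library (points) by strain, with the group mean as a line. The 3 global libraries lie highest for the pathogen response (519.3 to 805.5) and lowest for spermatogenesis (121.2 to 203.2), while vitellogenins spread widely within strains.

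Germ cell transcripts fell in the global knockout. Spermatogenesis genes fell in 40 of 44 cases and rose in 1 (40 and 1 adjusted over the list alone; median -4.22, adjusted p = 6.77e-18, and adjusted p = 0.518 with an estimated correlation). Among them were spe-44, a regulator of the sperm programme (4.84 against 35.3 CPM, -2.87), spe-4 (-3.68) and the Argonaute alg-3 (-4.94). Their summed level was 121.2 to 203.2 CPM in the global libraries, with the second muscle library next at 235.6. Germline and oogenesis genes fell in 13 of 70 cases and rose in 0 (11 and 0 adjusted over the list alone; median -1.54, adjusted p = 4.1e-07, and adjusted p = 0.856 with an estimated correlation). Among them were the P granule genes pgl-1 (143 against 438 CPM, -1.61) and glh-1 (-0.83), the chromosome axis gene him-3 (-1.66) and the Argonaute csr-1 (-1.56), of which him-3 and csr-1 overlap other genes. The summed level of this list was 13930, 18540 and 26790 CPM in the third control, muscle and neuronal libraries and 3438 to 8041 in the 12 others. The 6 vitellogenins had a median of -1.14 and 0 calls (adjusted p = 0.453 for the list).

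Nervous system genes rose in the global knockout. Of 99 neuropeptide genes 55 rose and 2 fell (65 and 2 adjusted over the list alone; median 0.97, adjusted p = 7.16e-12, and adjusted p = 0.518 with an estimated correlation). These included nlp-14 (71.7 against 19.1 CPM, 1.91), nlp-21 (1.56), flp-21 (1.61) and flp-3 (1.23). The neuropeptide list also holds 11 nlp genes of the epidermal antimicrobial peptide list, which are thus counted in both. Of 59 pan-neuronal and synaptic genes 21 rose and 0 fell (23 and 1 adjusted over the list alone; median 0.78, adjusted p = 2.98e-06, and adjusted p = 0.7 with an estimated correlation). Among them were the dense core vesicle gene ida-1 (1.78), the peptide-processing enzymes egl-3 (1.77) and egl-21 (1.41), and unc-25, which makes GABA (1.17). Glial genes rose in 5 of 15 cases and fell in 0 (5 and 0 adjusted over the list alone; median 0.87, adjusted p = 0.00343, and adjusted p = 0.7 with an estimated correlation). Called members included itx-1 (1.43), delm-2 (3.75), snf-3 (1.16) and fig-1 (1.14). Insulin-like peptides rose in 9 of 30 cases and fell in 0 (9 and 1 adjusted over the list alone; median 0.49, adjusted p = 0.042, and adjusted p = 0.7 with an estimated correlation). Called members included ins-20 (7.54), ins-1 (1.35), ins-18 (1.48) and ins-17 (1.05). Body wall muscle genes rose in 7 of 52 cases and fell in 0 (3 and 0 adjusted over the list alone; median 0.40, adjusted p = 0.0204, and adjusted p = 0.961 with an estimated correlation). Among them were the myosin unc-54 (12200 against 5200 CPM, 1.22), unc-73 (1.24), tnt-2 (0.80) and dyb-1 (1.16). Pharyngeal genes rose in 7 of 24 cases and fell in 0 (7 and 0 adjusted over the list alone; median 0.57, adjusted p = 0.00577, and adjusted p = 0.7 with an estimated correlation). Called members included the gland genes phat-5 (4.2), phat-6 (1.05) and phat-3 (1.39) and the pharynx regulator pha-4 (1.51). With stage covariates the muscle and pharynx lists changed direction (adjusted p = 0.801 and 0.916), and the pan-neuronal and glial lists were not called (0.538 and 0.801). The muscle list was not called without control replicate 3 or global replicate 2 (adjusted p = 0.191 and 0.274), nor was the insulin-like list without control replicate 1 or 3 or global replicate 2 or 3 (0.0546, 0.067, 0.0877 and 0.0531). The neuromuscular junction list was not called (adjusted p = 0.707), and 1 of its 21 genes, nra-2, fell (-1.19; also 1 adjusted over the list alone). Of the 15 fits that leave out 1 library, fig-1 lost its call in 15 (adjusted p up to 0.239), snf-3 in 12 (0.144), dyb-1 in 8 (0.158), pha-4 in 4 (0.106), unc-54 in 3 (0.106) and tnt-2 in 2 (0.111). itx-1, delm-2 and phat-3 lost theirs in 1 each (0.0545, 0.0556 and 0.0513). nlp-21, unc-73 and dyb-1 overlap other genes.

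Transcripts of splicing factors and of metabolic genes also moved. Of 52 splicing factors 22 rose and 3 fell (24 and 5 adjusted over the list alone; median 0.45, adjusted p = 0.000139, and adjusted p = 0.7 with an estimated correlation). Among them were uaf-2, the small subunit of the U2 auxiliary factor (214 against 89.8 CPM, 1.25), the helicase ddx-23 (1.15), cyn-15 (0.94) and teg-1 (1.11). The 16 SMN, Sm and Lsm genes were not called as a list (median 0.04, mean -0.10, adjusted p = 0.707), and lsm-4 alone fell (-0.69, adjusted p = 0.0182, and 0.0653 without global replicate 2; 0 adjusted over the list alone). Fasting and fatty acid oxidation genes rose in 16 of 43 cases and fell in 4 (18 and 4 adjusted over the list alone; median 0.70, adjusted p = 0.00227, and adjusted p = 0.518 with an estimated correlation). The mitochondrial importer of fatty acids cpt-1 went from 97 ± 1.23 to 622 ± 97.3 CPM (2.68, SE 0.25, adjusted p = 9.47e-05), the glyoxylate cycle gene icl-1 from 371 ± 102 to 4170 ± 1360 (3.49), and acdh-11 rose by 1.12. Oxidative phosphorylation genes fell in 13 of 64 cases and rose in 0 (10 and 0 adjusted over the list alone; median -0.21, adjusted p = 0.0058, and adjusted p = 0.961 with an estimated correlation). Called members included nduf-6 (-0.89), cox-11 (-0.75), cox-19 (-0.95) and asb-1 (-1.25). The call was lost without global replicate 1 (adjusted p = 0.114) and with stage covariates (0.0803), as was that of the fasting list with these (0.187). cyn-15, teg-1, lsm-4 and nduf-6 overlap other genes.

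The other lists were not called as groups in the global knockout, though single members changed. Collagens rose in 11 and fell in 26 of 155 cases (8 and 11 adjusted over the list alone; median 0.15, mean -0.65, adjusted p = 0.703). Examples are bli-6 (-5.20) and col-138 (-5.07) against col-98 (3.02) and col-84 (2.89). Of 55 molting genes ptr-22 (5.64) rose and grl-27 (-3.43) and cut-4 (-1.45) fell (1 and 0 adjusted over the list alone; adjusted p = 0.792 for the list). Of 44 intestinal genes 9 rose and 5 fell (10 and 6 adjusted over the list alone; adjusted p = 0.212), including far-3 (5.97), pgp-1 (2.84), mrp-2 (1.41) and pho-1 (-1.48). Small heat shock genes hsp-16.2 (3.38), hsp-16.41 (3.76), hsp-16.48 (3.35) and hsp-16.1 (3.70) rose among 29 heat shock genes (0 adjusted over the list alone; adjusted p = 0.328). Of 28 genes of the endoplasmic reticulum stress response 3 rose and 4 fell (3 and 4 adjusted over the list alone; median 0.10, mean 0.06, test direction down, adjusted p = 0.953). The rises were in xbp-1 (1.15), the stress sensor pek-1 (1.18) and srp-7 (0.97), and a fall was in sec-61.G (-1.54). Of 19 mitochondrial stress genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.39), with haf-1 (1.28) up and tomm-22 (-0.91), phb-2 (-0.81) and mtx-2 (-0.58) down. Of 28 cell death and DNA damage genes 4 rose and 2 fell (1 and 1 adjusted over the list alone; median -0.12, mean 0.03, adjusted p = 0.846). The engulfment receptor ced-1 (1.69), atm-1 (0.89) and atl-1 (0.81) rose, and the p53 gene cep-1 (-1.38) fell. Of 38 fatty acid synthesis genes 7 rose and 8 fell (9 and 9 adjusted over the list alone; median -0.17, mean 0.01, adjusted p = 0.707), with acs-17 (2.10) and fat-2 (1.02) up and elo-5 (-1.48) and elo-1 (-1.11) down. Of 57 histone genes 3 rose and 4 fell (1 and 2 adjusted over the list alone; adjusted p = 0.759), with the sperm histone htas-1 (-4.47), his-70 (-3.59), his-9 (2.28) and his-35 (0.70). Of 82 ribosomal protein genes 3 rose and 3 fell (1 and 2 adjusted over the list alone; adjusted p = 0.592), with rpl-42 (-5.04), rpl-41.1 (-1.03), rpl-24.2 (0.87) and rpl-7A (0.58). Overlapping genes among those named here are col-84, far-3, pho-1, haf-1, phb-2, acs-17, elo-5 and rpl-7A. Several of these symbols, his-9, hsp-16.1 and hsp-16.48 among them, are carried by more than 1 near-identical gene, whose reads are hard to assign. Early embryo genes (13 tested, 1 rise, 1 adjusted over the list alone, adjusted p = 0.759), coelomocyte and excretory genes (16 tested, 0 calls, adjusted p = 0.792) and nonsense-mediated decay genes (26 tested, 0 calls, adjusted p = 0.707) completed the lists. Of the 15 fits that leave out 1 library, atl-1 lost its call in 12 (adjusted p up to 0.281) and atm-1 in 10 (0.214), and without global replicate 1 their values were 0.34 and 0.51. The call of his-35 was lost in 7 (0.136), that of rpl-7A in 6 (0.091), hsp-16.1 in 5 (0.161), hsp-16.41 in 4 (0.0862), hsp-16.48 and mrp-2 in 3 (0.105 and 0.0762), grl-27 and htas-1 in 2 (0.0572 and 0.055), and hsp-16.2 and his-9 in 1 (0.0516 and 0.0556).

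The intestinal knockout was made to remove smn-1 in the gut. Single genes of several kinds rose. The ABC transporter pgp-8 (WBGene00004002, chromosome X, 10859301 to 10864422, an overlapping gene) went from 1.44 ± 0.533 to 55.6 ± 3.14 CPM (5.26, SE 0.39, adjusted p = 6.09e-06) and the glutathione transferase gst-24 from 7.35 ± 4.54 to 121 ± 37.8 (4.03, SE 0.68, adjusted p = 0.00676). The lectin clec-52 went from 15.4 ± 1.84 to 98.7 ± 26.3 (2.68, SE 0.35, adjusted p = 0.000944) and fbxa-163 from 0.103 ± 0.0778 to 38.6 ± 4.92 (8.32, SE 0.93, adjusted p = 0.000291). gst-24 lost its call without control replicate 2 or 3 (adjusted p = 0.0765 and 0.0516). The protease asp-5 fell from 816 ± 78.8 to 382 ± 72.5 CPM (-1.1, adjusted p = 0.0184), as did the glucuronosyl transferases ugt-47 (-1.35, an overlapping gene) and ugt-53 (-2.26). asp-5 lost its call in 9 of the 15 fits that leave out 1 library, with an adjusted p of up to 0.17 (without intestinal replicate 3). In all, 136 genes were higher and 116 lower, or 60 and 11 without overlapping genes. The balance turns with the setting: 274 and 388 by DESeq2, 313 and 357 with stage covariates, and 71 and 88, 62 and 87, and 81 and 95 without control replicate 1, 2 or 3. Of these 252 calls, 152 were also made in the same direction in the neuronal knockout, where 1.2 would be shared by independent lists, and 100 were not (75 higher and 25 lower). F26F4.2 lost its call in 3 of the 15 fits (adjusted p up to 0.0634) and psf-2 in 1 (0.0553). The shared calls include the largest changes of all, and 107 of the 152 (70.4%) lie in genes whose exons overlap another gene, against 30.3% of genes tested. They include tct-1 (0 against 805 ± 20.7 CPM, at least 19000-fold lower), popl-7 (at least 1510-fold), sym-2 (1460), T13F3.6 (1160), hmg-11 (682), Y39A1A.24 (532), exos-4.1 (421) and klp-11 (270). nuo-3 (-10.71), lev-10 (-8.63) and cox-14 (-6.68) also fell. In the other direction went C46G7.1 (0 in the control, at least 535-fold higher), F26F4.2 (246), the 2 ribosomal RNA genes named rrn-1.1 (11.78 and 10.77), cpg-7 (8.88), spcs-2 (7.40) and psf-2 (7.39). The 18 genes just named, from tct-1 on, all overlap other genes. The intestinal and neuronal libraries were counted on another set of gene models than the control, so that these shared changes and the gene models are confounded. The count of called genes was 159, 149 and 167 without control replicate 1, control replicate 2 and intestinal replicate 3, and 670 with stage covariates. It was 416 with rows by annotation order, 403 with the replicate block and 154 with only the groups compared.

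By lists, 10 were called in the intestinal knockout, each with adjusted p = 0.975 with an estimated correlation. Intracellular pathogen response genes had a median of 0.56 (adjusted p = 0.00219), with 3 members up and 1 down (5 and 1 adjusted over the list alone): fbxa-158 (6.55), fbxa-182 (3.08) and skr-5 (3.87, an overlapping gene) rose and pals-15 (-5.34) fell. skr-5 lost its call without control 1 or 3 or intestinal 2 or 3 (0.113, 0.117, 0.052 and 0.0952) and pals-15 without control 1 or intestinal 1, 2 or 3 (0.0553, 0.0798, 0.0575 and 0.0733). Splicing factors had a median of 0.19 (adjusted p = 0.00152), with rsp-7, an overlapping gene, rising (1.26; 5 adjusted over the list alone), and the SMN, Sm and Lsm list one of 0.30 (0.0435) with 0 members called. Neuropeptides had a median of 0.46 (9.22e-07), with nlp-53 rising (1.91; lost without control 1 or 2, 0.0577 and 0.0695). pals-15, rsp-7 and nlp-53 were also called the same way in the neuronal knockout (-4.36, 1.11 and 1.62), so that they too are confounded with the gene models. Those neuronal calls were lost in 14, 1 and 5 of the 15 fits that leave out 1 library (adjusted p up to 0.147, 0.108 and 0.209). The medians were, for insulin-like peptides 0.48 (0.0438), for DAF-16 targets 0.36 (0.0423) and for histones 0.42 (0.000331), with 1 member up and 1 down (5 and 1 adjusted over the list alone). The rise, of a his-9 gene, lost its call in 8 of the 15 fits (adjusted p up to 0.162). Vitellogenins had a median of -3.28 (0.00362) and germline and oogenesis genes one of -0.49 (0.00617), each with 0 members called. The summed vitellogenin level was 1151, 454.6 and 642.5 CPM in the intestinal libraries and 1857, 5645 and 16500 in the control. The neuromuscular junction list was called as lower (0.0438) by its mean of -0.34, which rests on lev-10, while its median was 0.07. Detoxification genes were not called as a list (adjusted p = 0.475); 2 rose, gst-24 and gst-15 (2.13), and 2 fell. gst-15 lost its call in 4 of the 15 fits that leave out 1 library (adjusted p up to 0.0892). Innate immunity (0.25) and oxidative phosphorylation (0.0605) were not called either. Calls lost without 1 library were those of DAF-16 targets (control 1, intestinal 1 or 3; adjusted p = 0.129, 0.236 and 0.0809), the SMN list (control 1 or 2, intestinal 3; 0.187, 0.0893 and 0.293) and the germline list (control 3, intestinal 2; 0.62 and 0.198). The insulin-like list was lost without control 1 or 3, muscle 1 or 3 or intestinal 3 (0.0691, 0.111, 0.0519, 0.0518 and 0.293). The neuromuscular list was lost without control 1 or 2, muscle 1, 2 or 3, global 1 or 3, or intestinal 1 or 3 (0.187, 0.12, 0.0519, 0.0592, 0.0518, 0.051, 0.0577, 0.0955 and 0.365). With stage covariates insulin-like peptides, histones and DAF-16 targets were not called (0.55, 0.0585 and 0.289).

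The neuronal knockout was made to remove smn-1 in neurons, the cells most affected when the human gene is lost. In this knockout 62 genes were higher and 97 lower (28 and 10 without overlapping genes), and 152 of these 159 are the calls shared with the intestinal knockout. The number of calls was 271 by DESeq2, 298 with rows by annotation order and 90 with only the groups compared. tct-1 was at 0 CPM (at least 24400-fold lower), as were sym-2 (1870), T13F3.6 (1480), hmg-11 (873), Y39A1A.24 (681), exos-4.1 (539) and klp-11 (346). popl-7 was at 0.00262 against 63.9 ± 3.35 CPM, nuo-3 changed by -12.33, lev-10 by -7.99 and cox-14 by -6.44. Higher were C46G7.1 (at least 677-fold), F26F4.2 (228), the rrn-1.1 genes (10.82 and 9.82), cpg-7 (8.57), psf-2 (7.78), spcs-2 (7.37) and picd-1 (2.80), and the genes named so far in this paragraph all overlap other genes. F26F4.2, spe-29 and psf-2 lost their calls in 5, 2 and 1 of the 15 fits that leave out 1 library (adjusted p up to 0.0915, 0.0613 and 0.0559). The transporter pgp-7 (19.5 ± 9.13 against 0.117 ± 0.0205 CPM, 7.32, adjusted p = 0.00171) and the globin glb-1 (23.6 ± 7.18 against 2.28 ± 0.224, 3.38, adjusted p = 0.00124) were higher too. Chosen after their values were seen, the 7 calls not made in the intestinal knockout were the sperm gene spe-29 (-5.34), the receptor gene srw-85 (-4.42), C08F11.7 (-2.28), noa-1 (-0.88), WBGene00014672 (-1.68), prdm-14 (-4.06) and smy-2 (7.19), of which spe-29 and noa-1 overlap other genes. Of these srw-85 alone differed between the knockouts in the direct contrast (6.32 higher in the intestinal, adjusted p = 0.00204). The pan-neuronal list (median 0.10, adjusted p = 0.654) and the neuropeptide list (median 0.03, adjusted p = 0.763) were not called. The 5 lists called (3 without control replicate 2, 10 without neuronal replicate 2 and 8 without neuronal replicate 3) were spermatogenesis (median -0.35, adjusted p = 0.00669), collagens (-0.18, 0.0389), molting (-0.35, 0.0172), ribosomal proteins (-0.14, 0.0119) and oxidative phosphorylation (-0.05, mean -0.34, 0.00224), with adjusted p = 0.928 with an estimated correlation for each. Their called members were spe-29 and, in the last list, nuo-3 and cox-14. The mean of the oxidative phosphorylation list rests largely on nuo-3 and cox-14, whose changes are confounded with the gene models. Without neuronal replicate 3 the molting list changed direction (adjusted p = 0.471). Calls lost without 1 library were spermatogenesis (control 3, neuronal 2; adjusted p = 0.114 and 0.985), molting (control 1 or 2; 0.125 and 0.323) and ribosomal proteins (control 3, neuronal 1 or 2; 0.114, 0.229 and 0.0602). Collagens were lost without control 2 or 3, neuronal 2 or 3, or intestinal 3 (0.379, 0.114, 0.0663, 0.366 and 0.0503). The neuronal knockout shares the intestinal knockout's confounded gene models.

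The muscle knockout, whose libraries share the control's gene models, differed from the control in 0 genes by edgeR's test, with 41 genes at an unadjusted p under 0.05 and 3 genes called by DESeq2. Those 3, named after their values were seen, are srw-85 (-4.55), C08F11.7 (-2.39) and WBGene00014672 (-1.3), and each was also called lower in the neuronal knockout. By edgeR srw-85 had the smallest adjusted p (5.09 ± 3.24 against 0.226 ± 0.136 CPM, -4.52, adjusted p = 0.172), and it was called without control replicate 3 (adjusted p = 0.0425). By lists, spermatogenesis genes had a median of -0.52 (adjusted p = 5.58e-13), collagens -0.11 (0.000341) and molting genes -0.15 (0.00835). Medians above 0 were those of pan-neuronal genes 0.18 (0.000229), body wall muscle genes 0.11 (0.00153), glial genes 0.33 (0.00153) and mitochondrial stress genes 0.21 (0.00153). The list of nonsense-mediated decay genes had 0.13 (0.00788) and that of splicing factors 0.09 (0.0183). Each had adjusted p = 0.998 with an estimated correlation, and 0 members called. With stage covariates none of the 8 lists tested was called: the body wall muscle and pan-neuronal lists changed direction (adjusted p = 0.804 and 0.836), and the 6 others had adjusted p = 0.208 to 0.991. Without muscle replicate 3 the molting list changed direction (0.376). Calls lost without 1 library were spermatogenesis (muscle 2; adjusted p = 0.188), pan-neuronal genes and glia (control 3 or muscle 2; 0.214 and 0.746, and 0.178 and 0.305) and collagens (control 2 or muscle 1; 0.144 and 0.0528). Body wall muscle and mitochondrial stress genes were lost without control 3, muscle 1 or muscle 2 (0.706, 0.106 and 0.305, and 0.0638, 0.0528 and 0.144), and molting genes without control 1 or 2 (0.284 and 0.393). Splicing factors and nonsense-mediated decay genes were lost without control 2, muscle 1 or muscle 3 (0.274, 0.12 and 0.293, and 0.0749, 0.0736 and 0.286). The spermatogenesis level of the second muscle library was 235.6 CPM, the lowest outside the global knockout. Replicate numbers paired these groups, and with the replicate block 0 genes were called. In simulated data of this comparison 4-fold changes were called in 59.7% of the genes that held one and 2-fold changes in 3%.

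Genes changed in a tissue knockout were then compared with those of the global knockout. The intestinal knockout shared 93 calls in the same direction (65 higher and 28 lower) and 7 in opposite directions, where independent lists would share 35.5. Simulations of unchanged groups with the same controls, 20 in number, shared 0, but they hold no effects and so do not measure what shared controls add to real calls. Part of the excess may come from the shared controls. These include fbxa-163, fbxa-158, pgp-8 (an overlapping gene), clec-52, gst-15 and gst-24, which rose by 5.25 in the global knockout. Of the 100 intestinal calls not made in the neuronal knockout 67 were shared with the global knockout, and of the 152 made in both 26 were. The neuronal knockout shared 26 calls with the global knockout (13 higher and 13 lower), with 7 in opposite directions, 22.4 under independence, and the muscle knockout shared 0, having no calls. Across genes, log2 fold changes correlated with those of the global knockout at 0.38 for the intestinal, 0.42 for the muscle and 0.11 for the neuronal knockout, against 0.49, 0.50 and 0.49 in the simulations. The covariances were 0.9, 0.362 and 0.203, or 0.678, 0.137 and -0.018 above the simulated ones; genes are not independent replicates. The intestinal count was 45, 33, 42 and 58 without control replicate 1, 2 or 3 or intestinal replicate 3. It was 205 with the replicate block, 333 by DESeq2, 191 with stage covariates, 57 with only the groups compared and 38 without overlapping genes. The neuronal count was 13, 12, 11, 14, 17 and 14 without control replicate 1, 2 or 3 or global replicate 1, 2 or 3. It was 47 by DESeq2, 9 with stage covariates and 7 without overlapping genes.

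Direct contrasts compared the knockouts with each other, and those of the intestinal or neuronal with the muscle or global knockout also hold the difference in gene models. The intestinal and neuronal libraries share their gene models, and 24 genes differed between them, 22 of them higher in the intestinal knockout and 2, F02E11.3 (-3.92) and ugt-53 (-2.17), lower. F08G2.5 (WBGene00008577, chromosome II, 13833095 to 13833631) was at 217 ± 62.1 CPM in the intestinal and 2.82 ± 0.0994 in the neuronal knockout (6.27, SE 0.35, adjusted p = 4.71e-06), and at 238 ± 29.7 in the global knockout and 2.53 ± 1.04 in the control. The overlapping gene pgp-8 was higher by 4.41 (adjusted p = 0.000262), F19B10.13 by 5.40, clc-32 by 7.33, clec-52 by 3.20 and srw-85 by 6.32 (19.1 ± 2.40 against 0.236 ± 0.132 CPM, with 5.09 ± 3.24 in the control). All 24 were called in the same direction in the global knockout against the control, 21 in the intestinal knockout against the control and 23 in the global against the muscle knockout, a contrast that shares no library with this one. With the replicate block 52 genes differed (32 higher and 20 lower), and the balance turned by DESeq2 (97 and 237) and with stage covariates (61 and 85). Among lists, neuropeptides (median 0.40, adjusted p = 1.85e-08), the intracellular pathogen response (0.60, 2.53e-06), ribosomal proteins (0.21, 2.53e-06), molting (0.55, 0.000442) and insulin-like peptides (0.54, 0.00109) were higher in the intestinal knockout. So were histones (0.39, 0.00109), antimicrobial peptides (0.83, 0.0282), innate immunity (0.24, 0.0292), SMN, Sm and Lsm proteins (0.26, 0.032), splicing factors (0.13, 0.032) and DAF-16 targets (0.24, 0.032). Germline genes (-0.91, 3.65e-07), vitellogenins (-4.46, 0.000442), nonsense-mediated decay (-0.23, 0.00704) and fatty acid synthesis (-0.23, 0.0175) were lower. Every one of the 15 had adjusted p = 0.821 to 0.922 with an estimated correlation. The oogenesis level of the third neuronal library was 26790 CPM, the highest of all 15, and without that library the germline and molting lists changed direction (adjusted p = 0.334 and 0.886). The gene count was 14, 15, 15, 8, 12, 8, 14 and 12 without control 2, muscle 1, global 3, neuronal 1, neuronal 2, neuronal 3, intestinal 1 and intestinal 3, and 1, F08G2.5, with only the 6 libraries compared. With stage covariates the molting and nonsense-mediated decay lists also changed direction (adjusted p = 0.0124 and 0.815), and insulin-like peptides, histones and DAF-16 targets were not called (0.169, 0.103 and 0.643). Of the other lists, neuropeptides, the pathogen response, ribosomal proteins and insulin-like peptides stayed called whichever library was left out. Histones were lost without neuronal 2 (0.0777), vitellogenins without neuronal 3 (0.0898), fatty acid synthesis without neuronal 2 or intestinal 3 (0.227 and 0.112) and nonsense-mediated decay without neuronal 3 or intestinal 3 (0.404 and 0.112). Antimicrobial peptides were lost without neuronal 1 or 2 or intestinal 3 (0.126, 0.0743 and 0.0916), innate immunity without neuronal 1 or 3 or intestinal 2 (0.126, 0.534 and 0.435), and DAF-16 targets without neuronal 1 or intestinal 1 or 3 (0.185, 0.361 and 0.0731). The SMN list was lost without neuronal 1 or 2 or intestinal 3 (0.199, 0.632 and 0.367), and splicing factors without neuronal 1 or 2 or intestinal 1 or 2 (0.376, 0.683, 0.219 and 0.164).

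**Figure D3:**
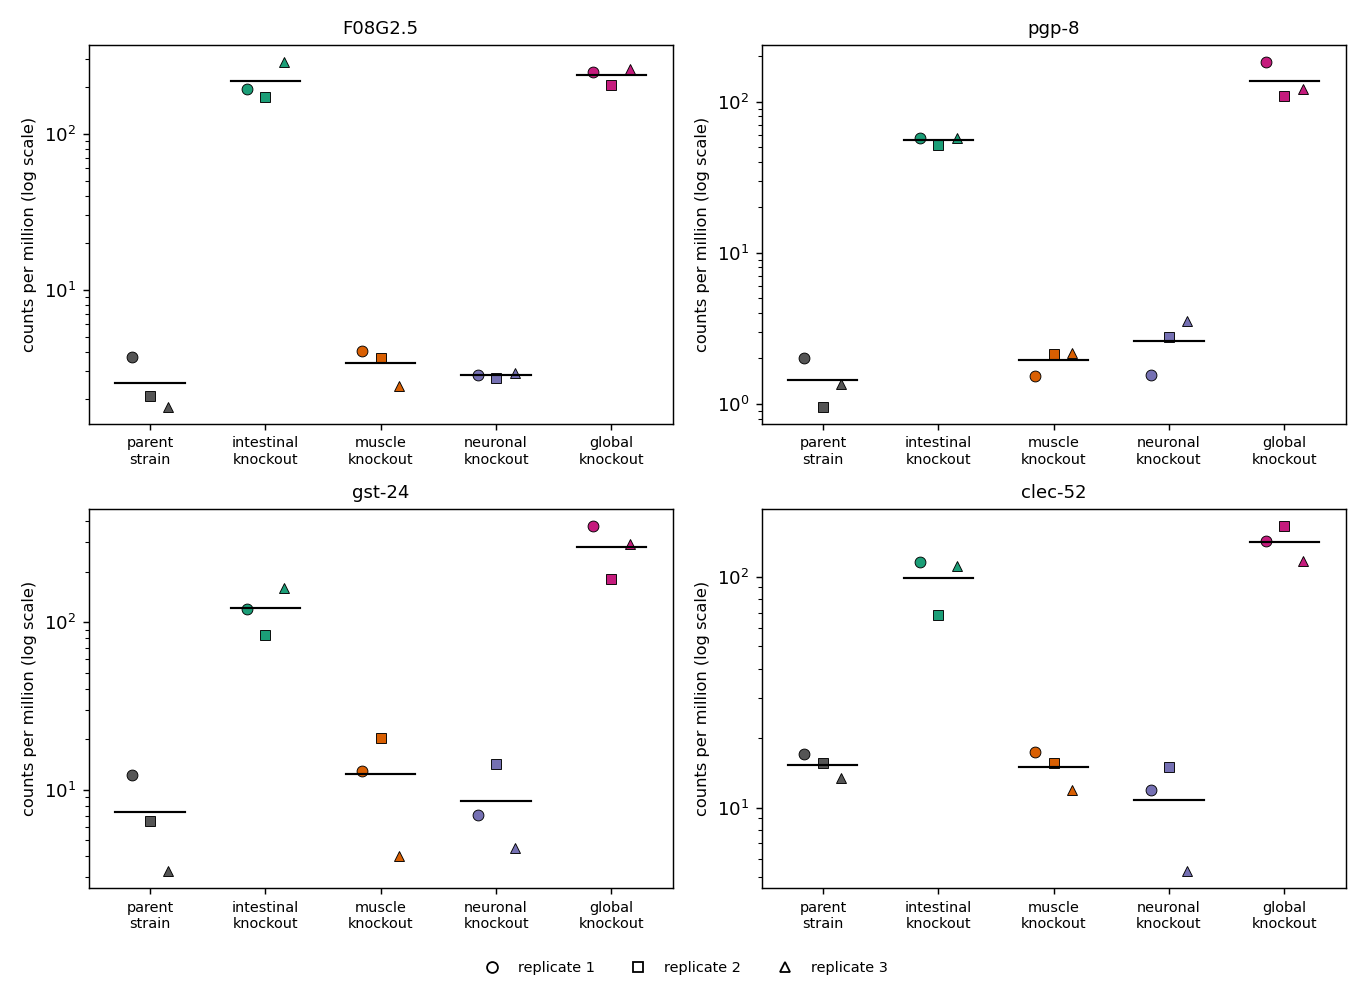
CPM (log axis) of F08G2.5, pgp-8 (an overlapping gene), gst-24 and clec-52 in each library (points) by strain, with the group mean as a line. F08G2.5 averaged 217 in the intestinal and 238 in the global knockout, against 2.53 in the control and 2.82 in the neuronal knockout.

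Against the global knockout, 3893 genes differed in the intestinal (2163 higher and 1730 lower), 3846 in the muscle (2041 and 1805) and 4931 in the neuronal knockout (2635 and 2296). These balances turn without global replicate 2 (1087 and 1261, 694 and 1256, and 1255 and 1656) and with stage covariates (249 and 396, 1290 and 1715, and 1055 and 1611). That of the muscle knockout also turns without global replicate 3 (589 and 824), without the 3 libraries with high yolk and oogenesis levels (908 and 1440) and with only the groups compared (773 and 1013). The muscle contrast, on common gene models, was led by genes that were high in the global knockout: F08G2.5 (-6.14, adjusted p = 5.63e-06), pgp-8 (-6.15), fbxa-182 (-5.04), T08E11.1 (-6.10), F26F2.1 (-6.15) and D2063.1 (-5.31), of which pgp-8 and D2063.1 overlap other genes. The intestinal and neuronal contrasts were led by overlapping genes: lev-10 (-9.16 and -8.53), tct-1 (at least 15400-fold and 19700-fold lower), popl-7, T28D9.1 (-5.18 and -5.45) and cox-14 (-6.20 and -5.96). F08G2.5 (-6.40) was among the first in the neuronal and R01B10.3 (at least 277-fold lower, an overlapping gene) in the intestinal contrast. Between the intestinal and muscle knockouts 238 genes were called (124 and 114), or 70 without overlapping genes (59 and 11), and the balance turned by DESeq2 (271 and 368), with stage covariates (164 and 176) and without muscle replicate 1, 2 or 3 (69 and 83, 69 and 89, and 76 and 95). Between the muscle and neuronal knockouts 162 were called (100 and 62; 160 with the replicate block), or 21 without overlapping genes, where the balance turns (4 and 17). Both contrasts were led by the same overlapping genes lev-10, popl-7, tct-1, T28D9.1, cox-14 and emc-6. Without the third global library these counts were 1952 for the intestinal, 1413 for the muscle and 2591 for the neuronal contrast. Other libraries that moved a count were global replicate 2 (2348, 1950 and 2911), intestinal replicate 3 (2159), muscle replicates 1 and 3 (2400 and 1823) and neuronal replicate 1 (3266). For the intestinal against the muscle knockout they were muscle replicates 1 and 2 and intestinal replicate 3 (152, 158 and 152).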

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

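All tests weighed here on the shared calls, the genes that differ and the pathogen response were chosen after the results were seen. The predictions for the splits of the libraries were also written after that, while the direct contrasts were planned.

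Direct contrasts of 2 knockouts called 3893 genes for the intestinal and global, 3846 for the muscle and global, 4931 for the neuronal and global, 238 for the intestinal and muscle, 24 for the intestinal and neuronal, and 162 for the muscle and neuronal knockouts. In those of the intestinal or neuronal with the muscle or global knockout the gene models differ too. Without overlapping genes the 238 and 162 fell to 70 and 21, so that these do not show by themselves that effects differ. The 3893 and 4931 fell to 2774 and 3545, in step with the 30.3% of genes left out, and the same difference in gene models gave 252 and 159 calls against the control, so that the gene models do not account for most of them. The share of reads aligned to several places, which no comparison of the report uses, was 11.3 ± 1.03% in the global libraries, above the control libraries at 7.3 ± 0.886%, with 8.22% in the muscle, 3.02% in the neuronal and 3.12% in the intestinal knockout. The 6 libraries of each contrast can be split in 10 ways, too few for a share under 0.05. Counting the real split, 1 split called as many genes in 8 comparisons, where the highest of the others called 0 against the real 252 (intestinal against control), 159 (neuronal), 4734 (global), 3893, 3846, 4931, 238 and 24. A mixed split places any difference between the groups, that of gene models included, in the spread within its sides. Few calls in the mixed splits were thus set in advance, and the 0 does not bear on the cause of the real calls. For muscle against control all 10 splits called 0, as the real one did. For muscle against neuronal, 2 of the 10 called as many as the real 162, and the highest other called 1678. That split sets muscle replicates 1 and 2 and neuronal replicate 2 against the rest, which points to a structure of the samples other than their groups.

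The first pattern is the 152 calls that the intestinal and neuronal knockouts share, against 1.2 expected of independent lists. The gene models change between these 6 libraries and the 9 others, as does the share of reads aligned to several places. Of the 152, 70.4% have exons that overlap another gene, against 30.3% of genes tested (odds ratio 5.57, Fisher's exact p = 2.9e-24, two-sided), which suggests that the gene models may account for many. An effect of smn-1 loss common to both tissues is argued against as the cause of most, since FLP in the global knockout removes smn-1 in both and yet 135 of the 152 differed from it the same way in both direct contrasts, with a median log2 fold change there of 0.22 in the direction of the call (quartiles -0.47 and 0.87) against 6.52 in the 2 knockouts. Such an effect in part of the 152 stays open and cannot be told apart from the gene models, since 26 were called the same way in the global knockout where 21.4 would be by independent draws.

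The second pattern is the 24 genes that differ between the intestinal and neuronal knockouts. Other gene models and the shared controls are argued against, since both groups share their gene models and 24 of the 24 were called the same way in the global knockout, counted on the control's models, where 3.4 would be by independent draws and 3 overlap another gene. Developmental stage as yolk, oogenesis and sperm levels measure it is argued against as the whole cause, since 22 of the 24 stayed called with those covariates and the median absolute log2 fold change was 3.68 against 3.96 without. Global knockout worms or RNA mixed into the intestinal libraries stay open. The 22 genes that were higher reached a median of 0.423 of their global excess (quartiles 0.278 and 0.83). Another 636 genes high in the global knockout, not called between the intestinal and neuronal knockouts, reached 0.0501 (0.00411 and 0.143). Genes were sorted by the same contrast that forms this share. A larger share in the 22 was thus set in advance, and the comparison cannot decide. A response to smn-1 loss in the intestine that the global knockout shares stays open. So do culture conditions common to those libraries and effects of FLP or strain background. These hypotheses were not tested.

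The third pattern is the rise of 29 intracellular pathogen response genes in the global knockout. Stage or germ cell content, as a steady trend with the same covariates, is argued against as the whole cause: the median log2 fold change of the 29 was 4.90 with the covariates and 4.71 without. The spermatogenesis levels of the global libraries (121.2 to 203.2 CPM) all lie below those of the 12 others (235.6 or more). The fit thus carries the trend beyond the other libraries, and a response that sets in only at such low levels stays open. With the covariates 19 of the 29 stayed called, and of the 10 others 9 had a smaller log2 fold change (median of the 10 2.16 against 2.94) and 10 a larger SE (1.05 against 0.69), while 1 kept a p low enough for a call without the covariates, so that stage stays open as a part of these 10. An infection or other exposure of the global cultures cannot be told apart from loss of smn-1, since all 3 of the 3 global libraries exceeded the 12 others in summed level and any exposure of these cultures coincides with their genotype. A defence response to smn-1 loss itself, and an effect of FLP or strain background, stay open and were not tested.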

How the results depend on the processing

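The alternatives on row matching, overlapping genes, the libraries of 1 file block, libraries that stand apart and stage covariates were chosen after the data were seen, and all others were planned.

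Under RLE, upper-quartile and restricted scaling, both filters and a fit without robust dispersion, each count of genes and of shared calls stayed within 1.5 times its value, as did each count of lists except 3 neuronal lists with upper-quartile scaling and 8 with no filter. The fall of smn-1 in the global knockout stayed called under every alternative that tested it. At an adjusted p under 0.01, called genes were 154 and 1873 (intestinal and global against control), 1104, 990 and 1537 (intestinal, muscle and neuronal against global) and 137 and 11 (intestinal against muscle and against neuronal). A minimum fold of 1.5 left 2722 in the global knockout. The replicate block gave 403 intestinal calls, 52 for intestinal against neuronal and 205 shared by intestinal and global. It also gave 6461 calls in the global knockout, in place of 4734. With only the groups compared, counts were 154 (intestinal), 90 (neuronal), 1786 (muscle against global), 2784 (neuronal against global), 98 (intestinal against muscle), 1 (intestinal against neuronal), 59 (muscle against neuronal) and 57 (shared, intestinal), with 4 residual degrees of freedom in place of 10. DESeq2 gave 662, 3 and 271 for intestinal, muscle and neuronal against control, 639, 334 and 260 for intestinal against muscle, intestinal against neuronal and muscle against neuronal, and 333, 1 and 47 shared calls. Rows by annotation order gave 416, 298, 393 and 302 (intestinal, neuronal, intestinal against muscle, muscle against neuronal). With them 17637 genes were tested in place of 16786, and the global knockout had 4990 calls in place of 4734. The row match used the levels, so it may leave out genes whose levels differ between the blocks. How far this lowers the counts was not tested. Identifiers as printed gave 16365, 16277, 16706, 16637, 16457, 204 and 16352 (intestinal, neuronal, each against global, intestinal against muscle and neuronal, muscle against neuronal), because they pair different genes. Without overlapping genes, 30.3% of those tested, some counts fell by more than that share. They were 71 (intestinal), 38 (neuronal), 70 (intestinal against muscle) and 21 (muscle against neuronal), with 38 and 7 shared calls. The 6 libraries of the longer block alone gave 1 for intestinal against neuronal. Leaving out the 3 libraries that stand apart gave 2348 (muscle against global), 9 (intestinal against neuronal) and 15 (shared, neuronal). Stage covariates gave 670 (intestinal), 1806 (global), 645 and 2666 (intestinal and neuronal against global), 146 (intestinal against neuronal), 191 and 9 (shared). An estimated inter-gene correlation left 0 lists called in each of the 5 comparisons with list tests, against 10, 9, 5, 16 and 15 with the preset one.

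Results that reversed under stage covariates were the body wall muscle and pan-neuronal lists in muscle (adjusted p = 0.804 and 0.836), body wall muscle and pharynx in the global knockout (0.801 and 0.916), molting and nonsense-mediated decay for intestinal against neuronal (0.0124 and 0.815), and grl-27 (0.29), cut-4 (0.14) and snf-3 (-0.46) in the global knockout. Without 1 library the molting list in muscle ranged in adjusted p from 1.18e-06 to 0.393, in neuronal from 5.12e-05 to 0.471 and for intestinal against neuronal from 3.74e-07 to 0.886, and the germline list there from 1.35e-16 to 0.334. Stage covariates also ended the calls of 3 lists in the intestinal, 6 in the muscle and 6 in the global knockout and 3 for intestinal against neuronal. The causes of these changes were not tested.

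Leaving out 1 library at a time gave smn-1 changes of -0.39 to -0.18 (intestinal), -0.10 to 0.14 (muscle), -0.06 to 0.29 (neuronal) and -5.96 to -3.92 (global). Called genes ranged from 149 to 264 (intestinal), 0 to 1 (muscle), 116 to 160 (neuronal) and 2862 to 5269 (global), and direct contrasts from 1952 to 4269, 1413 to 4409 and 2591 to 5975 (intestinal, muscle and neuronal against global), 152 to 274 (intestinal against muscle), 8 to 24 (intestinal against neuronal) and 115 to 159 (muscle against neuronal). Shared calls ranged from 33 to 104 (intestinal), 0 to 0 (muscle) and 11 to 30 (neuronal), and lists called from 8 to 11, 6 to 11, 3 to 10, 14 to 16 and 12 to 17. Of the named genes called against the control, 10 of 36 in the intestinal, 6 of 27 in the neuronal and 30 in the global knockout lost their call without at least 1 library, and none reversed. Lists were not run under DESeq2 or the row and overlap alternatives. In simulated data 2-fold changes were called in at most 11.9% of the genes that held one.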

Other observations

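Gene classes, chromosomes and bins by intron number were chosen after the data were seen, while the correlation with intron number was predicted before its result was seen.

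Gene classes grouped by the letters of their names moved in the global knockout (298 one-sided Fisher's exact tests, 1 per class and direction, Benjamini-Hochberg adjusted). Mitochondrial ribosomal proteins fell, 22 of 38 mrpl genes (median log2 fold change -0.51, adjusted p = 2.88e-08) and 18 of 29 mrps genes (-0.58, 1.94e-07), with 0 rising in either class. Receptor guanylyl cyclases rose in 15 of 30 cases (gcy; median 1.22, adjusted p = 0.000136) and osm genes, several of which build cilia, in 7 of 10 (1.23, 0.00268). The chemoreceptor classes srd, sre, srg, srh, sri, srt, srx and str passed no threshold (adjusted p = 0.335 for sri higher and 1 for the others). Nuclear hormone receptors rose in 56 of 218 cases and fell in 3 (nhr; median 0.66, adjusted p = 0.000152), cytochrome P450 genes in 20 of 67 (cyp; 0.95, 0.0135), glutathione transferases in 15 of 43 (gst; 1.2, 0.0109) and autophagy genes in 6 of 11 (atg; 0.66, 0.0318). Further classes past the threshold were daf (11 of 24 rose and 1 fell; 0.88, 0.0042), ttr (17 of 57 rose and 9 fell; 0.5, 0.0296) and irld (9 of 20 fell and 1 rose; -0.32, 0.0154). Of 13 prp genes, which encode pre-mRNA processing factors, 8 rose and 0 fell (median 0.71, adjusted p = 0.00276). F-box genes rose in 38 of 138 cases and fell in 11 (fbxa; 0.69, 0.000886), and neprilysin-like peptidases fell in 11 of 23 and rose in 3 (nep; -3.24, 0.00276). All 67 cyp and 43 gst genes, 9 of the 13 prp and 3 of the 138 fbxa genes are also in the lists of detoxification, splicing factors and the pathogen response. Other classes that overlap the lists moved the same way: spe fell in 24 of 28 cases (1.15e-14), and flp rose in 21 of 30 (7.6e-10), nlp in 31 of 66 (1.48e-08), and pals in 16 of 26 (1.53e-06). Fisher's test takes the genes of a class as independent. With an estimated inter-gene correlation none of the lists stayed called in this knockout.

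Falls in the global knockout were fewer on the X chromosome, where 5.6% of 2378 genes fell, than on the autosomes, where 15.5% of 14408 fell (Fisher's exact p = 1.17e-45, two-sided). Rises were alike in share, 14.5% against 14.1% (Fisher's exact p = 0.567). Germline and sperm genes, whose lists fell, were not left out of these shares. Genes of 1 chromosome are not independent of each other.

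The hypothesis was that loss of a splicing assembly factor would lower transcripts with many introns. Across 15780 protein-coding genes, Spearman's rho of the log2 fold change in the global knockout with the number of introns was 0.10, the opposite sign, and it was 0.10 without the germline, sperm and early embryo lists and 0.11 given the mean level. Those lists hold 70, 44 and 13 tested genes, too few to remove germ cell transcripts from such a correlation. Of 1762 genes with over 10 introns 17.2% rose and 6.4% fell (median 0.35), and of 283 without introns 12.4% rose and 19.1% fell (median -0.06). The values in the intestinal, muscle and neuronal knockouts were -0.13, 0.12 and 0.00. With 0 genes called in the muscle knockout, a rho of this size is not particular to the global knockout. These counts per gene give no measure of unspliced reads, so splicing itself was not examined, and genes are not independent replicates.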
